A study of Mus musculus with 6 samples.

How the data were processed

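RNA was extracted with TRIzol from 6 GT1-7 cultures, 3 control and 3 treated with AVP, and sequenced on an Illumina instrument, per the labels' protocols. All 6 samples carry the same batch label. The deposited tables hold whole-number counts per gene symbol, 1 table per sample, which the authors made from their reads. The genome builds mm10 and GRCm38 are named per the submitters' processing notes; the aligner, the counting tool, the annotation, the use of strand and the library chemistry are not given in the sources used here. Without knowledge of strand or of how shared reads were treated, counts of overlapping genes, antisense pairs and near-identical copies are uncertain. The 24391 rows were in the same order in all tables. Of these, 27 gene symbols had been turned into dates by a spreadsheet, and they were kept as unnamed rows (23 tested, 19 changed). No mitochondrially encoded gene was among the rows that matched the list. The tables hold no columns of per-sample values outside the sample map.

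Counts were analysed with edgeR 4.0.16 and limma 3.58.1 in R 4.3.3. Genes were filtered with filterByExpr (minimum count 10), libraries were scaled with TMM factors, and AVP was compared with control in 1 model of all 6 samples without covariates, using the robust quasi-likelihood F test and Benjamini-Hochberg adjustment at 0.05. Log2 fold changes are AVP minus control, and the SE is the absolute log2 fold change divided by the square root of F. CPM values of tested genes are TMM-scaled, and those of the receptor genes and markers with few counts are CPM of the total counts. The 95% counting intervals and the floor of 3 counts cover counting error only, since reads are not independent molecules. Adjusted p-values of genes come from edgeR. Principal components were computed on log2 CPM with a prior count of 2. Group differences in library measures were tested with exact two-sided permutation tests, for which 3 against 3 cannot go below 0.1.

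Gene lists were tested with camera from limma (preset correlation 0.01, lists of at least 5 tested members), with an estimated correlation and with fry, which asks whether the genes of a list move on balance one way and does not compare them with other genes. Named genes followed a fixed rule. It took Gnrh1, Avpr1a, Avpr1b, Avpr2, Oxtr and Kiss1r whatever their values, then the 12 largest rises and 12 largest falls among genes past the threshold with a mean of at least 5 CPM and no overlap between the groups, without unnamed gene models and pseudogenes. From each list that passed it took up to 4 members with the smallest p in the direction of the list, and from other described lists up to 3 with the smallest p. Other members named in the text were chosen after their values were seen, and some genes that the rule takes are not reported here. Gene positions come from GENCODE M21 (GRCm38), matched by unique symbol for 13587 tested genes (95.9%).

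The test was run on simulated counts drawn from the real means and library sizes for AVP against control, where 14043 genes were tested. Of genes changed by log2 0.58, 1 and 2, it recovered 81.8%, 88.1% and 97.0%, and 4.84% of its calls were false. A simulated raised list of 20 genes gave a camera p of 2.17e-202 and an unchanged list 0.975. Only 66, 67 and 66 genes were changed at these sizes, a far smaller share than was called in the real data. Genes were also drawn independently of each other, unlike members of a real list. The simulated share of false calls and list p-values therefore do not carry over to the real tests. The alternatives were DESeq2 1.42.0, RLE and upper-quartile factors, library size alone, no filter, a mean of at least 50 counts, limma-voom, limma-trend, robust estimation off, an adjusted p under 0.01, a fold change of 1.2 (glmTreat), the replicate number as a block, each sample left out in turn and, added after the data were seen, Rn45s left out and libraries thinned to the smallest total. A pseudocount alternative did not apply to counts. Tables were handled with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.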

Results

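RNA sequencing measured transcript levels in GT1-7 cells, an immortalised mouse hypothalamic line described as resembling gonadotropin-releasing hormone (GnRH) neurons. After 12 h of serum starvation, 3 cultures received vehicle and 3 received arginine vasopressin (AVP), a peptide hormone of the hypothalamus, at 200 pg/mL for 6 h. The labels call the cultures of each group biological replicates. The control cultures are called vehicle controls in one label and untreated in another, and the difference could not be settled from the labels. Total counts per library were 36826004, 35986533 and 34908867 in control replicates 1, 2 and 3 and 36257545, 37418318 and 35597040 in AVP replicates 1, 2 and 3 (exact two-sided permutation p = 0.5, smallest possible 0.1). At this depth 3 counts in a library correspond to 0.0802 to 0.0859 CPM, the count scaled to library size that is used throughout. Of 24391 gene rows, 18477 had at least 1 count and 14163 were tested.

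The question of the design was which transcripts differ between AVP-treated and control GT1-7 cells. AVP-treated and control libraries separated fully on the first principal component, which held 84.4% of the variance of the 500 most variable genes. Pearson correlations of log2 CPM across genes lay between 0.989 and 0.994 within a group and between 0.962 and 0.967 between groups (genes are not independent replicates). Counts of any 2 libraries of a group differed by more than sampling noise, with a chi-square per degree of freedom of 7.52 or more, so no library was counted as a duplicate. Control replicate 1 held 0.995% of its counts on Rn45s, the ribosomal RNA precursor (95% Clopper-Pearson interval 0.992 to 0.998%, counting error only), against 0.139 to 0.245% in the other 5 libraries. The AVP libraries had more detected genes, 16674 to 16739 against 16166 to 16403 in the control libraries (exact two-sided permutation p = 0.1, the smallest possible). The nuclear RNA Malat1 was measured at 1556 ± 129 CPM with AVP and 813 ± 303 CPM in control libraries (SD, n = 3), and its adjusted p of 0.0686 missed the threshold.

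**Figure D1:**
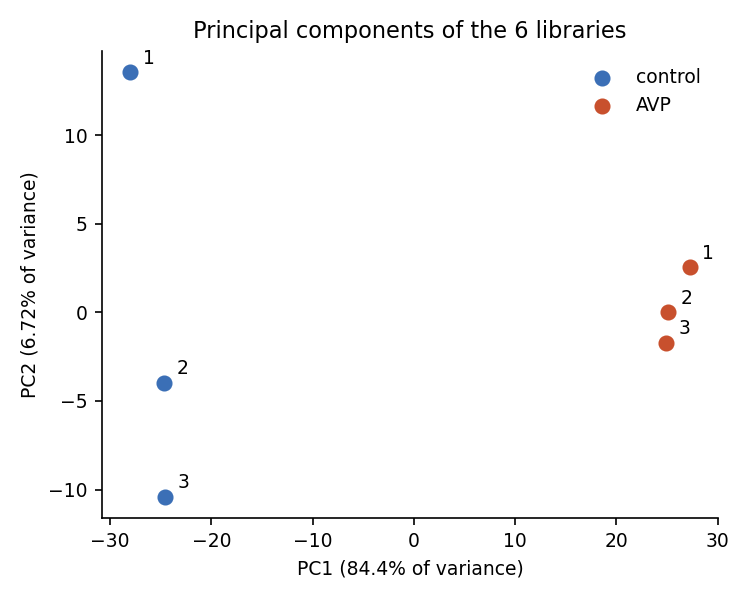
Principal components of log2 CPM of the 500 most variable genes, first component (84.4% of variance) on the x axis and the second (6.72%) on the y axis; each point is a library, numbered by replicate. The control libraries lie at negative and the AVP libraries at positive values of the first component, and control replicate 1 lies apart from the other libraries on the second.

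AVP was accompanied by differences in most of the measured transcriptome. At an adjusted p under 0.05, 4063 genes rose and 4084 fell with AVP, together 8147 or 57.5% of the tested genes. Most of the changes were small, with a median absolute log2 fold change of 0.47 among these genes, and 737 genes rose and 679 fell by at least 2-fold. The 3 AVP values and the 3 control values did not overlap for 8983 tested genes (63.4%, where chance gives 10%). The spread between replicates was low, with a biological coefficient of variation of 7.48%. Against a fold change of 1.2 rather than any change, 2197 genes rose and 2332 fell, and without control replicate 1 the counts at the main threshold were 3818 and 3896. Among genes with a mean of at least 50 counts, 453 rose and 528 fell by at least 2-fold, so falls outnumbered rises there.

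**Figure D2:**
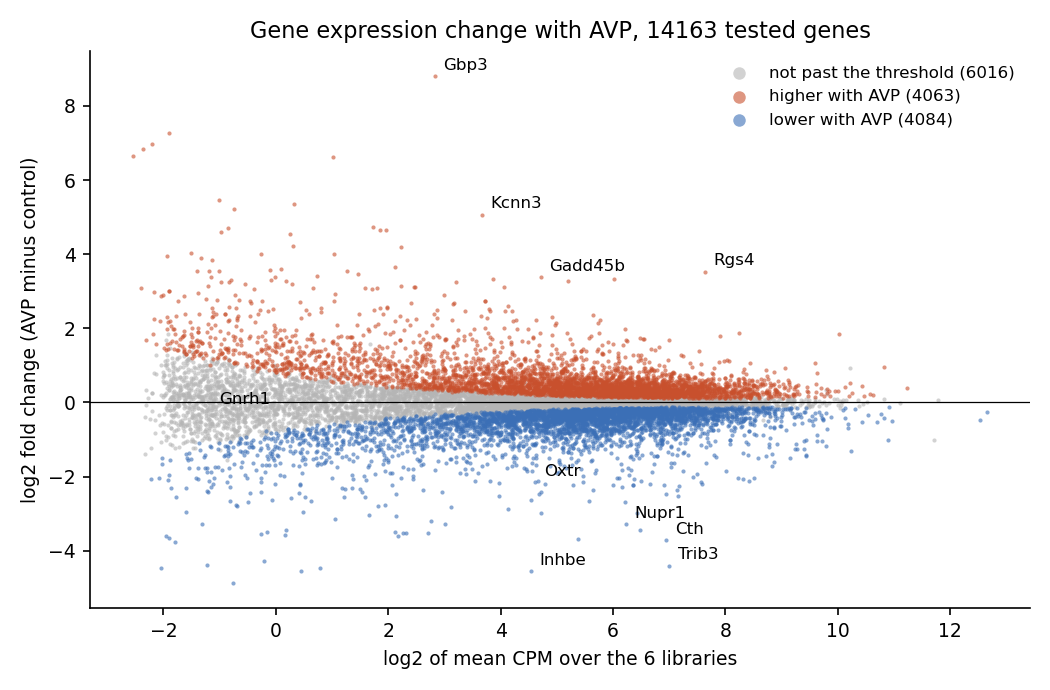
Log2 fold change (AVP minus control, y axis) against the log2 of the mean CPM over the 6 libraries (x axis) for the 14163 tested genes. Orange points rose (4063), blue points fell (4084) and grey points did not pass the threshold (6016).

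The receptors through which AVP is known to act were close to or below the counting floor, and the related oxytocin receptor fell. Avpr1b had 0 counts in all 6 libraries, which allows up to 0.0278 CPM in the control group and 0.0275 CPM in the AVP group. Avpr1a had 2 counts over the control libraries and 1 over the AVP libraries, and Avpr2 had 2 and 7, so none of these genes was tested and no fold is given. Oxtr, the oxytocin receptor gene (GRCm38 chromosome 6, 112473683 to 112489943, minus strand), which can also bind AVP, fell from 40.1 ± 1.73 to 9.09 ± 1.21 CPM (SD, n = 3; log2 fold change -2.14, SE 0.10, adjusted p = 1.23e-10). Gnrh1, the gene that encodes GnRH (chromosome 14, 67745181 to 67749439, plus strand), was measured at 0.483 ± 0.236 CPM in control and 0.418 ± 0.148 CPM in AVP libraries, from 11 to 26 counts per library (adjusted p = 0.734). Kiss1r, the kisspeptin receptor gene, was measured at 1.99 ± 0.376 and 2.05 ± 0.172 CPM (adjusted p = 0.887).

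The largest rises with AVP included genes of ion transport, G protein signalling and axon guidance. Gbp3, an interferon-inducible GTPase gene (chromosome 3, 142560026 to 142573209, plus strand), had 3 counts over the control libraries and 1572 over the AVP libraries, a ratio of 517 with a 95% counting interval of 176 to 2508. Kcnn3, which encodes a small-conductance calcium-activated potassium channel, rose from 0.733 ± 0.0969 to 24.7 ± 2.99 CPM. Rgs4, a regulator that shortens G protein signalling (chromosome 1, 169741477 to 169747642, minus strand), rose from 31.8 ± 4.33 to 367 ± 6.82 CPM, the highest AVP level among the 12 largest rises. The stress-inducible Gadd45b, the membrane protein gene Tmem119, the secretin gene Sct and the plasma membrane calcium pump gene Atp2b4 rose by 3.28 to 3.38 on the log2 scale. Unc5c, a netrin receptor gene, Sema3c, a secreted guidance cue, Dlx2, a homeobox factor, Zim1, an imprinted zinc finger gene, and Axl, a receptor tyrosine kinase gene, rose by 2.90 to 3.24. All 12 genes were higher in 3 of 3 AVP libraries than in any control library, which the rule that chose them required. Members of the guanylate-binding protein family resemble each other, and because the counting method is not given in the sources used here the count of Gbp3 is uncertain to that extent.

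Of the 12 largest falls, Trib3, Cth, Slc7a11, Chac1 and Nupr1 were members of the amino acid response list. Inhbe, an inhibin subunit gene (chromosome 10, 127348857 to 127354411, minus strand), fell from 44.7 ± 2.59 to 1.9 ± 0.712 CPM (log2 fold change -4.55, SE 0.17, adjusted p = 4.83e-11). Trib3, a pseudokinase gene induced by stress (chromosome 2, 152337422 to 152344032, minus strand), fell from 245 ± 37.6 to 11.5 ± 1.33 CPM. Cth, an enzyme of cysteine synthesis, fell 13.1-fold, Slc7a11, the cystine transporter gene, fell 12.8-fold, and Chac1, a glutathione-degrading enzyme gene, fell 10.8-fold. Mmp23 and Fgf21, the latter a secreted metabolic hormone gene, each fell 11.5-fold. Nupr1, a stress-inducible nuclear protein gene, fell from 136 ± 7.68 to 13.9 ± 0.915 CPM (adjusted p = 5.87e-14). Sspo, Cass4, the glycine transporter gene Slc6a9 and the cytochrome oxidase subunit gene Cox6a2 fell by 2.99 to 3.27 on the log2 scale. All 12 genes were lower in 3 of 3 AVP libraries than in any control library, which the rule that chose them required.

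**Figure D3:**
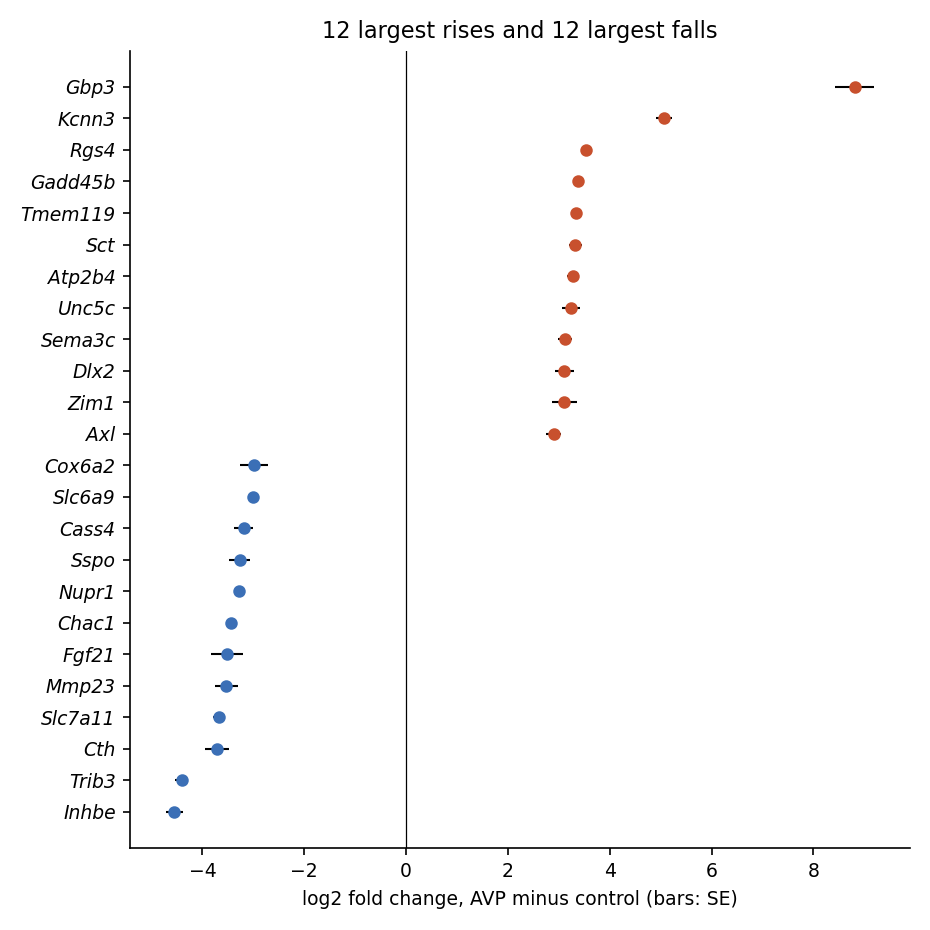
Log2 fold change (AVP minus control, x axis) with its SE for the 12 genes with the largest rise and the 12 with the largest fall; orange points rose and blue points fell. The fitted value of Gbp3 (8.81) rests on 3 control counts.

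Of 40 gene lists fixed before the data were examined, 34 had at least 5 tested members, and 13 passed the camera test with a preset correlation of 0.01, 9 higher and 4 lower with AVP. None of the 34 passed with an estimated correlation (lowest adjusted p = 0.0748), where 5 had an unadjusted p under 0.05, and fry passed 20. In the lists that passed with the preset, the estimate lay above 0.01 in all but the NF-kB list. It was 0.249 for the amino acid response and 0.67 for cholesterol synthesis, so the preset lies far below the estimate there. Among the 9 other ways of dividing the 6 libraries into 3 and 3, the preset test gave 6 to 13 lists. Each of those ways puts AVP and control libraries on both sides, so part of the AVP difference stays. Those counts therefore do not show how many lists chance gives. Each AVP library had more detected genes and more Malat1 than any control library, and the list tests did not account for either measure. Counts adjusted over the list alone equalled those over all genes in 28 of the 39 lists with tested members.

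Genes of the amino acid response, targets of the transcription factor ATF4, fell together. All 20 measured members fell, 20 also when adjusted over the list alone (17 were called without AVP replicate 2 and 19 without control replicate 1, 2 or 3), with a median log2 fold change of -1.66 (camera adjusted p = 3.17e-51; adjusted p = 0.0748 with an estimated correlation). Beside Nupr1 and Slc7a11, Pck2, the mitochondrial phosphoenolpyruvate carboxykinase gene, fell from 308 ± 9.13 to 69.3 ± 5.82 CPM, and Mthfd2, of mitochondrial folate metabolism, fell from 699 ± 35.5 to 215 ± 4.48 CPM. Atf4 itself fell by 1.45 on the log2 scale. The unfolded protein response list fell on balance, with 8 members lower, 4 higher and 9 not past the threshold (camera adjusted p = 0.000544; adjusted p = 0.542 with an estimated correlation). Its falls were led by Ddit3 (128 ± 9.92 to 20.1 ± 0.612 CPM), Ppp1r15a and Herpud1, and Ddit3 and Ppp1r15a are also known ATF4 targets. The chaperone gene Hspa5 was at 1377 CPM in control and 1293 CPM in AVP libraries and did not pass the threshold, and Hsp90b1 fell by 0.52 on the log2 scale.

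**Figure D4:**
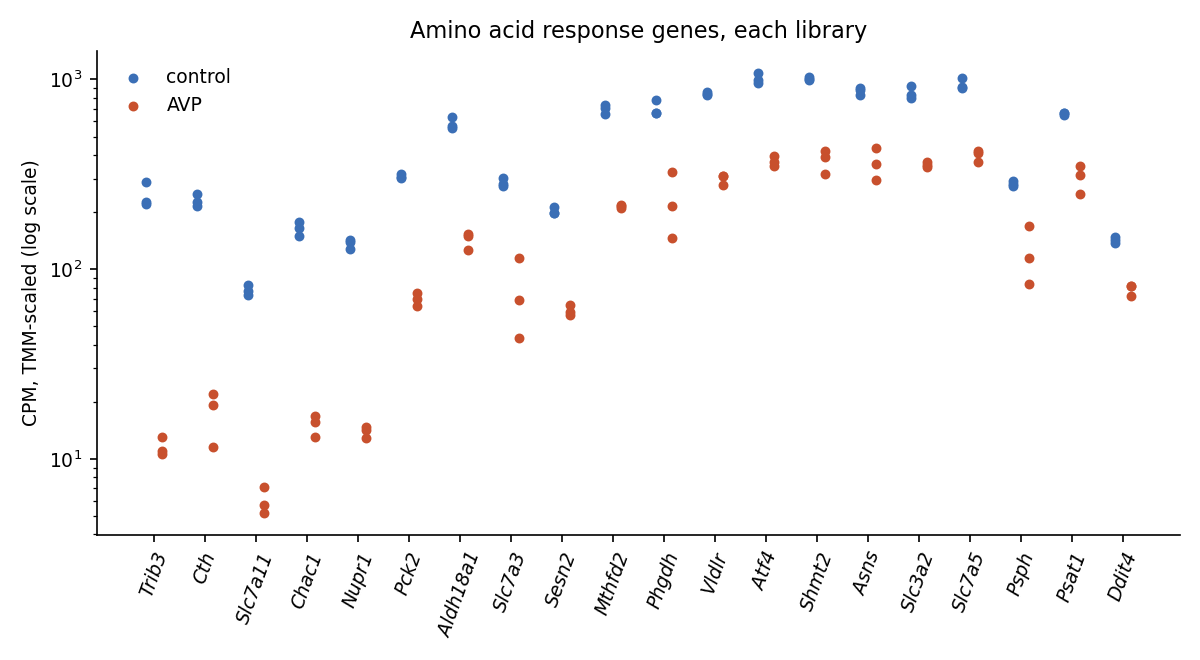
CPM (TMM-scaled, log axis) of the 20 amino acid response genes in each library; blue points are the 3 control and orange points the 3 AVP libraries, with genes ordered by log2 fold change from Trib3 (-4.41) to Ddit4 (-0.86). Every AVP value lies below every control value of the same gene.

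Cholesterol synthesis genes fell as a group, with 20 members lower, 1 higher and 2 not past the threshold, or 21 lower adjusted over the list alone (median log2 fold change -0.71; camera adjusted p = 1.82e-11; adjusted p = 0.391 with an estimated correlation). Fdft1, squalene synthase, fell from 108 ± 5.15 to 34 ± 2.56 CPM, and Tmem97, Msmo1 and Cyp51 fell by 1.44, 1.41 and 1.03 on the log2 scale. Autophagy and lysosome genes were lower by small amounts, 17 lower and 2 higher of 25, with a median of -0.21 (camera adjusted p = 0.0495; adjusted p = 0.592 with an estimated correlation). Sqstm1, an autophagy adaptor gene, fell from 680 ± 45.5 to 407 ± 32.2 CPM, and Hexa, Atg9a and Gabarap fell by 0.46, 0.49 and 0.35. The call for autophagy was lost with library size alone (0.0604) and without control replicate 2 (0.0706), AVP replicate 1 (0.0583) or AVP replicate 2 (0.0512). It was also lost with the replicate number as a block.

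Targets of TGF-beta and YAP signalling rose, with 10 of 16 measured members higher, 2 lower and 4 not past the threshold (median log2 fold change 1.02; camera adjusted p = 2.51e-10; adjusted p = 0.148 with an estimated correlation). The members that rose were led by Id2 (19.1 ± 0.415 to 89.8 ± 8.67 CPM), Id3, Smad7 and Skil, inhibitors of differentiation and feedback regulators of SMAD signalling. Of the YAP targets, Amotl2 fell by 0.47 and Cyr61 had a log2 fold change of 0.22 that did not pass the threshold. Of p53 targets and apoptosis genes, 14 rose and 4 fell (median 0.42; camera adjusted p = 5.82e-06; adjusted p = 0.275 with an estimated correlation). Ccng1, cyclin G1, rose from 107 ± 1.19 to 370 ± 6.71 CPM, the death receptor gene Fas from 0.638 ± 0.108 to 8.07 ± 0.0525 CPM, and Eda2r and Aen by 1.88 and 0.96. Gdf15, a member of this list, fell by 2.22.

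NF-kB and inflammatory genes rose, 11 higher and 2 lower of 14 (median 1.49; camera adjusted p = 0.000302; adjusted p = 0.148 with an estimated correlation). Nfkb2 rose from 36.6 ± 1.56 to 108 ± 4.13 CPM and Nfkbia, which encodes the inhibitor IkB-alpha, from 51.3 ± 4.05 to 124 ± 4.81 CPM, while Icam1 and Nfkbie rose by 4.66 and 1.78 from low control levels. The chemokine gene Cxcl12 in this list fell by 1.97. Interferon-stimulated genes were higher in 11 of 19 measured members and lower in 0, with a median of 0.41 (camera adjusted p = 0.00512; adjusted p = 0.389 with an estimated correlation). Gbp3 stays the highest member at the lower bound of its counting interval, so the median is the same there by construction. Next to Gbp3 they were led by Cxcl10 (0.453 ± 0.123 to 5.06 ± 1.28 CPM), Irf7 and Usp18.

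CREB targets rose, 11 higher and 2 lower of 15 (median 0.53; camera adjusted p = 0.000302; adjusted p = 0.402 with an estimated correlation). The neuropeptide precursor gene Vgf rose from 161 ± 5.68 to 359 ± 42.9 CPM, and Gem, Pde4b and Dusp1 rose by 1.34, 1.01 and 1.33, whereas the neurotrophin gene Bdnf fell by 0.39. In the list of vasopressin and oxytocin receptors and Gq signalling, 8 members rose and 4 fell of 15 tested, or 8 and 6 adjusted over the list alone (median 0.24; camera adjusted p = 0.0449; adjusted p = 0.436 with an estimated correlation). Rgs4, Plcb3, Itpr1 and Rgs2 rose, by 3.53, 0.68, 0.57 and 0.94, and the call was lost without control replicate 2 (0.0836) or AVP replicate 3 (0.0593). Oxtr, the only receptor of this list that was tested, fell by 2.14. Rgs4 shortens G protein signalling, so the call does not show higher Gq signalling. How far the call rests on Rgs4 was not tested.

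Axon guidance and synapse genes rose, 18 higher and 3 lower of 30 (median 0.39; camera adjusted p = 8.15e-06; adjusted p = 0.179 with an estimated correlation). Unc5b, a netrin receptor gene, rose from 16.3 ± 1.12 to 84.3 ± 1.57 CPM, and Sema3a and its receptor gene Nrp1 rose by 1.58 and 1.38. Ribosome biogenesis genes rose by small amounts, 15 higher and 1 lower of 23, or 16 higher adjusted over the list alone (median 0.27; camera adjusted p = 0.000544; adjusted p = 0.391 with an estimated correlation), with Utp20, Nop2, Dkc1 and Rrp9 rising by 0.50 to 0.81. Heat shock genes rose, 10 higher and 2 lower of 14, or 11 higher adjusted over the list alone (median 0.38; camera adjusted p = 0.00949; adjusted p = 0.391 with an estimated correlation). Hspa8 rose from 1234 ± 129 to 2402 ± 237 CPM, and Stip1, Hsp90aa1 and Hsp90ab1 rose by 0.50, 0.41 and 0.40; chaperone genes have near-identical copies, so their counts are uncertain to that extent.

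**Figure D5:**
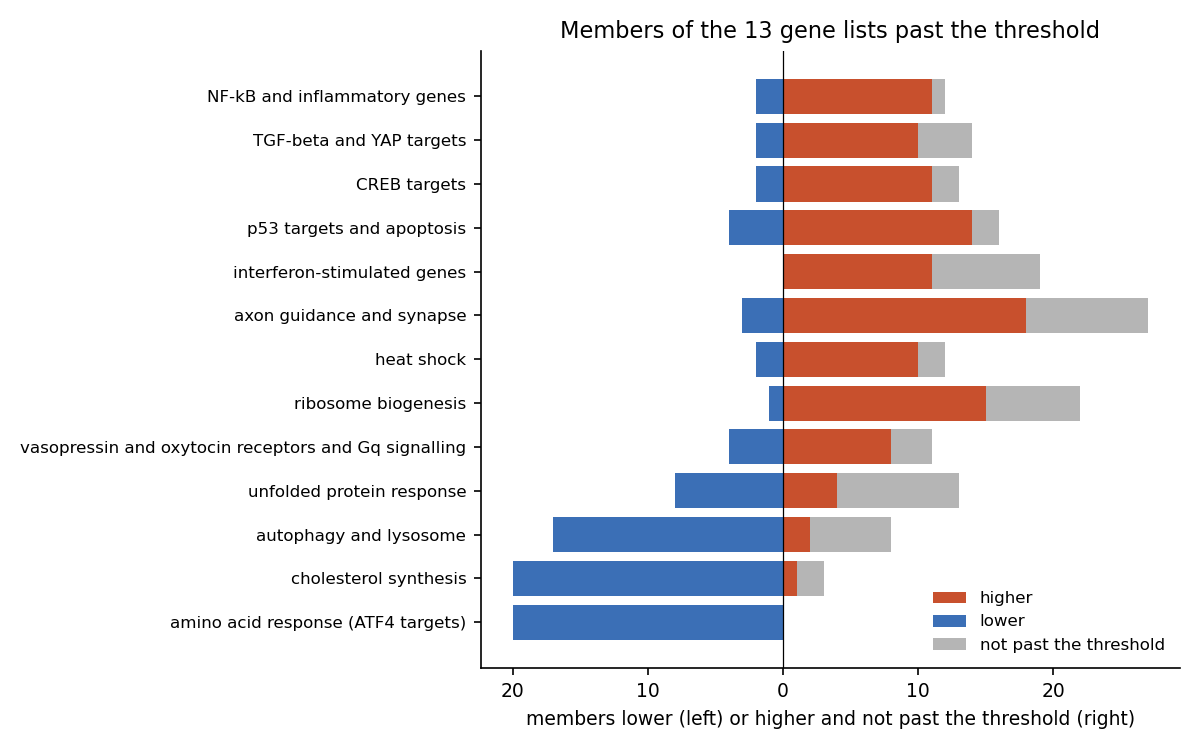
Number of members lower (blue, left), higher (orange, right) and not past the threshold (grey) in the 13 gene lists that passed the camera test, ordered by median log2 fold change. All 20 amino acid response genes lie on the left, and 11 of 19 interferon-stimulated genes lie on the right with none on the left.

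The remaining lists did not pass the camera test, and their members are given as counts. Immediate early genes were 10 higher and 3 lower of 22 (adjusted p = 0.0517), or 10 and 4 adjusted over the list alone. Junb, Fosl2 and Btg2 rose by 1.73, 1.10 and 0.92. The list passed without control replicate 1 (0.0399), AVP replicate 1 (0.0115) or AVP replicate 2 (0.0438), and with the replicate number as a block. Genes of G2 and mitosis were 15 lower and 0 higher of 25 (adjusted p = 0.0517), with Cdc20, Aurkb and Bub1b falling by 0.59, 0.46 and 0.62, and the list passed with RLE factors (0.0489) and without control replicate 1 (0.0151), AVP replicate 1 (0.00741) or AVP replicate 2 (0.0355). S phase genes were 5 higher and 13 lower of 25 (adjusted p = 0.775), with Ccne2, Rrm2 and Tyms rising and E2f1 and Ung falling. Of the GnRH gene and its transcription factors, 4 rose and 7 fell of 18 (adjusted p = 0.949), with Dlx2 and Isl1 rising and Nfib falling. Receptors for reproductive and metabolic signals were 10 higher and 4 lower of 21 (adjusted p = 0.105), where the oestrogen-binding receptor gene Gper1 and the progesterone receptor gene Pgr rose and the prolactin receptor gene Prlr fell. MAP kinase feedback genes were 6 higher and 5 lower of 15 (adjusted p = 0.999), with Dusp7 falling and Dusp5 and Spry2 rising.

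Neuronal lists moved in both directions. Neuropeptide secretion and vesicle exocytosis genes were 10 higher and 8 lower of 25 (adjusted p = 0.668), with Vgf rising and Chga and Cadps2 falling. Calcium channel and calcium signalling genes were 9 higher and 8 lower of 25 (adjusted p = 0.668), or 10 and 8 adjusted over the list alone. Calb1 rose and Cacna1h and Cacna1a fell. Potassium and sodium channel genes were 9 higher and 6 lower of 21 (adjusted p = 0.105), led by the rises of Kcnn3, Kcnq3 and Kcnn2. Circadian clock genes were 9 higher and 9 lower of 20 (adjusted p = 0.731), or 10 and 9 adjusted over the list alone. Ciart and Cry2 fell by 2.46 and 1.04 and Rorb rose by 0.80. In 6 lists the median, the mean and the direction of the test did not share a sign. These were the MAP kinase, clock, neuropeptide secretion, potassium and sodium channel, GnRH and NRF2 lists.

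Fatty acid and lipid genes were 6 higher and 9 lower of 23 (adjusted p = 0.364), or 8 and 10 adjusted over the list alone. Fads1 fell from 1708 to 693 CPM, Fads2 fell and Fasn rose. Glycolysis and hypoxia targets were 6 higher and 11 lower of 25 (adjusted p = 0.105), or 7 and 11 adjusted over the list alone. Hk1, Hk2 and Ndrg1 fell, and the list passed without control replicate 3 (0.0400). Nuclear-encoded oxidative phosphorylation genes were 4 higher and 10 lower of 40 (adjusted p = 0.581), or 2 and 7 adjusted over the list alone. Ndufa2 and Sdhc fell and Ndufv2 rose. NRF2 targets were 8 higher and 7 lower of 20 (adjusted p = 0.461), or 9 and 7 adjusted over the list alone. Slc7a11 and Osgin1 fell and Nqo1 rose. Cytosolic ribosomal protein genes, which share reads with pseudogenes, were 7 higher and 22 lower of 55 (adjusted p = 0.407), with Rpl12 and Rpl10a rising and Rpl4 and Rpl8 falling, and passed without control replicate 3 (0.0141). Replication-dependent histones were 0 higher and 2 lower of 7 (adjusted p = 0.461), with Hist1h1c and H1f0 falling, the latter a replication-independent linker histone gene. Nuclear long noncoding RNAs were 3 higher and 0 lower of 7 (adjusted p = 0.161), with Snhg1, Gas5 and Snhg11 rising, and passed without control replicate 3 (0.0275). Snhg11 lost its call without control replicate 1 (adjusted p = 0.0876), AVP replicate 1 (0.0502) or AVP replicate 3 (0.101). Wnt targets were 3 higher and 1 lower of 9 (adjusted p = 0.105; Lef1 and Znrf3 rose, Apcdd1 fell), Notch targets 7 higher and 3 lower of 12 (adjusted p = 0.731; Dtx4 and Dll1 fell, Hes1 rose), and extracellular matrix and adhesion genes 11 higher and 7 lower of 23 (adjusted p = 0.668; Itga6 and Itga5 fell, Lama1 rose). The list of mitochondrially encoded genes had 0 members among the rows and was not analysed here.

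Markers of other cell types were mostly below 1 CPM. In the control group, 7 of 9 astrocyte, 6 of 9 oligodendrocyte, 10 of 12 microglia and macrophage, 8 of 11 fibroblast, 7 of 8 endothelial and 8 of 8 epithelial markers lay under 1 CPM. The exceptions included Slc1a2 (118 ± 10.1 to 199 ± 27.4 CPM) and Fgfr3 among astrocyte markers, which rose, and Mbp and Cnp among oligodendrocyte markers, which fell. Of the microglia list Tmem119 and Cd68 rose, the latter not past the threshold without AVP replicate 3 (adjusted p = 0.0672), while Ptprc, Csf1r and Aif1 stayed at 5 counts or fewer in every library. Pdgfra and Col1a2 of the fibroblast list and Kdr of the endothelial list fell, the last from 319 ± 15.1 to 263 ± 17 CPM; the endothelial list, with 5 tested members, had an adjusted p of 0.731. The astrocyte list had too few tested members (4) for the list test, and 5 without control replicate 1, 2 or 3 or AVP replicate 3, at adjusted p of 0.0493, 0.0631, 0.0599 and 0.0578. Krt7 of the epithelial list rose from 0.171 ± 0.152 to 1.72 ± 0.273 CPM.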

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

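The tests without Rn45s and with thinned libraries were chosen after the data were seen. No gene called by the main test and by an alternative changed direction between them; leaving out Rn45s gave 4064 higher and 4083 lower, and thinning gave 4060 and 4066. DESeq2 gave 3905 higher and 4046 lower genes and library size alone 4475 and 3722. Against a fold change of 1.2, 2197 rose and 2332 fell, by construction of a stricter test. With a mean of at least 50 counts 453 rose and 528 fell by at least 2-fold, with fewer genes tested. Leaving out 1 library gave 3525 to 4053 higher and 3592 to 4166 lower genes, 688 to 813 and 656 to 732 at 2-fold, and 8 to 11 lists higher and 3 to 6 lower. With an estimated correlation camera called 0 lists higher and 0 lower (4 and 1 at an unadjusted p under 0.05). A correlation above the preset 0.01 raises the p-values of camera. In the lists that passed, the estimate lay above 0.01 in all but the NF-kB list (-0.0119). That list also lost its call (adjusted p = 0.148), so a higher correlation alone does not account for every loss. What else contributed was not tested. Fry, which does not compare a list with other genes, called 14 higher and 6 lower. The first component held 75.1% of the variance over all tested genes. Deviations of same-numbered samples correlated at 0.0787, -0.0452 and 0.0384. No effect shared by samples of the same number was seen, which does not show how the dishes were set up. With the replicate number as a block 3972 genes were higher and 3969 lower. The block gave 10 lists higher and 3 lower, without autophagy and lysosome and with immediate early genes. Of 2030 pairs of a named gene and an alternative, 2012 kept their call, 12 lost and 3 gained it (Snhg11 and Cd68 among the losses), and 3 reversed, none past the threshold. Those were Gnrh1 at 0.24 without control replicate 3 (range without 1 library -0.52 to 0.24), and Kiss1r at -0.12 without control replicate 3 and -0.03 without AVP replicate 2 (range -0.12 to 0.14). Control replicate 3 held the most Gnrh1 counts of its group (26, against 11 and 14) and the fewest Kiss1r counts (54, against 78 and 80). AVP replicate 2 held the most Kiss1r counts of its group (85, against 71 and 71). Leaving out these libraries moved small fold changes past 0. Lists far from the threshold also reversed. The MAP kinase list had adjusted p of 0.993 with the block, 0.998 with library size alone, and 0.981, 0.958 and 0.861 without control replicate 1, control replicate 3 and AVP replicate 1. The GnRH list had 0.718 (fry with the block), 0.967 (without control replicate 2) and 0.953 (without AVP replicate 1), with a range of 0.823 to 0.967 without 1 library. Depth limits statements on genes below about 1 CPM, among them Gnrh1 and the vasopressin receptor genes.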

Other observations

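The gene lists of the first 2 paragraphs, and the tests of Gnrh1, of library totals and of windows along chromosomes, were chosen after the data were seen, so their directions are not independent evidence. Adjusted p-values with an estimated correlation are over these 8 lists. Cytosolic aminoacyl-tRNA synthetase genes were 15 lower and 3 higher of 20 (median log2 fold change -0.87, adjusted p = 0.0224 with an estimated correlation), with Lars falling from 496 to 184 CPM and Dars rising by 0.48. Amino acid transporter genes were 12 lower and 5 higher of 23 (adjusted p = 0.0224), among them Slc6a9, Slc1a4 and Slc1a5, and 4 that are also in the amino acid response list (Slc7a11, Slc3a2, Slc7a5 and Slc7a3), while the taurine transporter gene Slc6a6 rose by 0.60. Peptide and growth factor ligand genes were 8 lower and 3 higher of 15 (adjusted p = 0.162), with Stc2, Gdf15 and Igf1 falling and Sct, Vgf and Stc1 rising. Genes of the translocon and COPII vesicles were 10 lower and 5 higher of 26 (adjusted p = 0.76).

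BMP targets were 14 higher and 1 lower of 15 (median 1.70, adjusted p = 0.0224 with an estimated correlation); Atoh8, Runx2, Smad6 and Smad9 rose by 2.24, 2.23, 1.70 and 1.57, and the BMP antagonist gene Nog rose by 1.12. Of these 15 genes, Id1, Id2, Id3, Id4, Bambi and Smad7 are also in the TGF-beta list, Hey1 in the Notch list and Msx1 in the GnRH list. Developmental transcription factor genes were 9 higher and 3 lower of 19 (adjusted p = 0.0461), with Tbx20 and Tbx3 rising by 2.20 and 1.68 and Hmx3 falling by 1.36; Dlx1, Dlx2, Isl1 and Six3 are also in the GnRH list. Imprinted genes were 12 higher and 4 lower of 19 (adjusted p = 0.26), with Peg3 rising from 130 to 474 CPM and Grb10 falling from 304 to 98.2 CPM. Cytoskeletal SRF and MRTF targets were 3 higher and 2 lower of 15 (adjusted p = 0.76). Besides Gbp3, Ccl20 (2 control counts against 108; ratio 53.2, 95% counting interval 14.4 to 445) and Scn4b (3 against 129; ratio 42.4, interval 14.2 to 208) were almost uncounted in the control libraries.

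Of the tested genes, 57.5% changed. Each AVP library had more detected genes and more Malat1 than any control library, and each group is confounded with its dishes. A difference in culture state between the dishes could therefore not be told apart from an effect of AVP on these genes. The mean totals of the groups differed by 1.44%, less than the SD of 2.62% within a group, and their ranges overlapped, which argues against a difference in depth. The chromosome median farthest from that of all genes was that of X, at 0.097 on the log2 scale, which argues against a gain or loss of whole chromosomes in the dishes of one group; the largest deviation of a window of 101 neighbouring genes was -0.27 on chromosome 7, more than the 0.244 reached in 100 shuffles, so smaller segments remain open. Of the 10 splits of the 6 samples into 3 and 3, 1 gave as many genes, and 1 as many at 2-fold (8147 and 1416; highest other 0 and 0), and 4 gave as many lists (13; highest other 13), and 10 splits are too few for a share under 0.05. Mixed splits still hold AVP and control libraries on both sides. The difference between the groups then enters the spread within each side, which fixes a low count of genes in advance. Part of that difference also stays between the sides, so lists can still pass. The mixed splits therefore give no chance rate for genes or lists.

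All 20 amino acid response genes fell in the main test. The median over the other 4 scalings nearest to 0 was -1.62, which argues against scaling, and without control replicate 1, the library with the most Rn45s reads, 19 of the 20 genes were called lower with a list median of -1.61, which argues against that library alone. Without it Psph lost its call, at -1.18 (SE 0.35) against -1.20 (SE 0.28) with all libraries, where the SE grew. Psph also lost its call without control replicate 2 or 3, and 17 genes were called without AVP replicate 2, where Psph, Phgdh and Slc7a3 were lost. A difference in medium or culture state between the dishes, such as more amino acid depletion in the control dishes, may account for the same fall. The aminoacyl-tRNA synthetase median of -0.87 goes the way both this and an effect of AVP on the pathway predict, so they cannot be told apart, since each group is confounded with its dishes. Measured amino acids or the medium change of each dish could help to separate them.

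Gnrh1 was under 1 CPM in all 6 libraries of a line described as GnRH neuron-like. No exon bases of Gnrh1 are shared with another gene in GENCODE M21 (0% of 642). This argues against reads lost to an overlapping gene under that annotation, while the annotation used for the deposited counts is not given. A population of cells other than GnRH-producing GT1-7 cells could give this pattern. Of the 24 listed GnRH genes and factors in the files, 15 reached 1 CPM in the control group and 9 did not. Gnrh1 itself is counted among those 9, as are Otx2, Six6 and Vax1. Without a reference library of the line this count cannot decide. Another population and low Gnrh1 transcription in GT1-7 cells under these conditions both stay open.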
